A study of Mus musculus with 10 samples.

How the data were processed

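Liver RNA of C57BL/6 mice on a high-fat diet (HFD) for 8 weeks was sequenced in 10 samples, 5 of wild type and 5 with a liver knockout of Cpt1a. Groups and replicate numbers were taken from the genotype labels and sample titles. The table's columns name the wild type libraries by another abbreviation (CON), and these were matched to the wild type titles by their number. The labels name separate samples but do not say that each came from its own animal, so the p-values measure the spread between these samples. No pair of libraries agreed within counting noise (smallest chi-square per degree of freedom between 2 libraries 29.79).

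Per the submitters' processing notes, reads were handled with fastp, HISAT and RSEM on GRCm38.p5. Versions and settings are not given in the sources used here, nor is whether the library or the counting kept strand. The authors deposited 1 table of 51911 genes with an expected (estimated) count and a TPM value per library, a gene length, and their own comparison as a log2 fold change and a p-value. Of the deposited expected counts, 7.68% were not whole, and all were rounded to whole numbers before testing. The deposited TPM values were read and summed per library but not tested. The authors' log2 fold changes lie closer to 0 than those of the fit used here, and whether the deposited p-value was adjusted is not stated. A further 5 rows held no gene, 3 of them empty, and were left out. A spreadsheet had turned 27 gene symbols into dates, of which 26 were restored by gene identifier. Coordinates and gene types come from the GENCODE M21 annotation of GRCm38, which held 51632 of the 51911 identifiers.

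The total count per library ran from 20599078 to 26955922. At that depth a count of 3 corresponds to between 0.111 and 0.146 CPM, counts scaled per library to a common total, and this covers counting error only. Genes were filtered with filterByExpr at its defaults, which left 13619 genes, and scaled with TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust = TRUE) on genotype, with a Benjamini-Hochberg adjusted p under 0.05 taken as a changed level. Standard errors were derived from the test's F statistic. CPM values are TMM-normalised and given as mean ± SD. Log2 fold changes are knockout against wild type.

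Before the data were examined, 48 gene lists were written, with 1055 symbols, of which 947 were measured. Lists with at least 5 measured members were tested, which left 46. The list of sex-chromosome transcripts (4 measured) and that of pancreatic and gut markers (2 measured) were not tested. Each list was compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Other tests of each list were fry and an exact permutation of its mean per library. Cpt1a itself was kept out of the lists that contain its partners.

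The rule for named genes was also set before the data were examined. It took Cpt1a and Fgf21, then up to 12 rises and 12 falls among changed genes with a mean log2 CPM of at least 0 and no overlap between genotypes. It added up to 4 changed members of each list that moved, in the list's direction, and up to 2 of each other list. Predicted genes were left out of the rule. Gm15441 and B930025P03Rik, and list members whose adjusted p did not pass, were chosen after their values were seen, the latter from the members with the smallest p in their list or those that passed adjusted over the list alone. The result for 1 gene that the rule takes is not reported here.

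The tests were tried on 20 simulated data sets, drawn from the means, library sizes and dispersions of the 13619 genes with 200 genes changed. On average 94% of genes changed 4-fold, 64.1% of those changed 2-fold and 17.6% of those changed 1.5-fold were recovered. False calls made up 5.6% of calls on average, between 1.8% and 12.3% in single data sets. In 1 simulation of lists of 25 genes, 6 of 6 lists shifted by 0.3 on the log2 scale and 0 of 40 unshifted lists were called. All of these simulations, of genes and of lists, drew genes independently of each other, so they hold no structure shared by libraries.

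Alternatives were other scalings, other filters, DESeq2 (1.42.0), limma-voom with library weights, edgeR without robust estimation, the replicate number as a block, and each library left out in turn. Further ones were added after seeing the data, namely surrogate variables (sva 3.50.0), a GC content and length offset, the removal of wild type replicates 1 and 2, and the exact permutation of list means.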

Results

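Hepatic transcript levels were measured by RNA sequencing in 10 liver samples of mice fed a high-fat diet for 8 weeks, 5 of wild type and 5 with a liver knockout of Cpt1a. Cpt1a encodes carnitine palmitoyltransferase 1A, the enzyme of the outer mitochondrial membrane that commits long-chain fatty acids to oxidation in the liver. Total counts lay between 20599078 and 26955922 in wild type and between 23990970 and 25200273 in knockout libraries. The single comparison asks how the liver transcriptome differs when hepatic Cpt1a is missing under this diet, with Fgf21, the hormone named in the title of the series, as a gene of interest.

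Cpt1a fell in the knockout from 430.1 ± 85.8 to 80.0 ± 9.19 CPM (SD, n = 5 each), a log2 fold change of -2.43 ± 0.16 (SE, edgeR adjusted p = 1.9e-05). Wild type libraries lay between 319.7 and 503.7 CPM and knockout libraries between 70.5 and 93.9 CPM, so all 10 libraries matched their labels. Cpt1a (ENSMUSG00000024900) lies on chromosome 19 at 3322334 to 3385733 of GRCm38, and its counts cover the whole gene, since the sources used here do not say which exons were removed. Cpt1b, the muscle-type isoform of the enzyme, rose from 0.891 ± 0.68 to 6.84 ± 2.73 CPM (log2 fold change 2.88 ± 0.47, adjusted p = 0.032) and stayed far below the remaining Cpt1a level. Cpt2, the partner enzyme of the inner membrane, was at 187.9 ± 13.9 and 184.6 ± 27.4 CPM (log2 fold change -0.03 ± 0.12, adjusted p = 1.0). The Cpt2 value changed sign in 4 of 23 alternatives and was never called. Cpt1c had 47 counts in all in each genotype and was not tested.

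**Figure D1:**
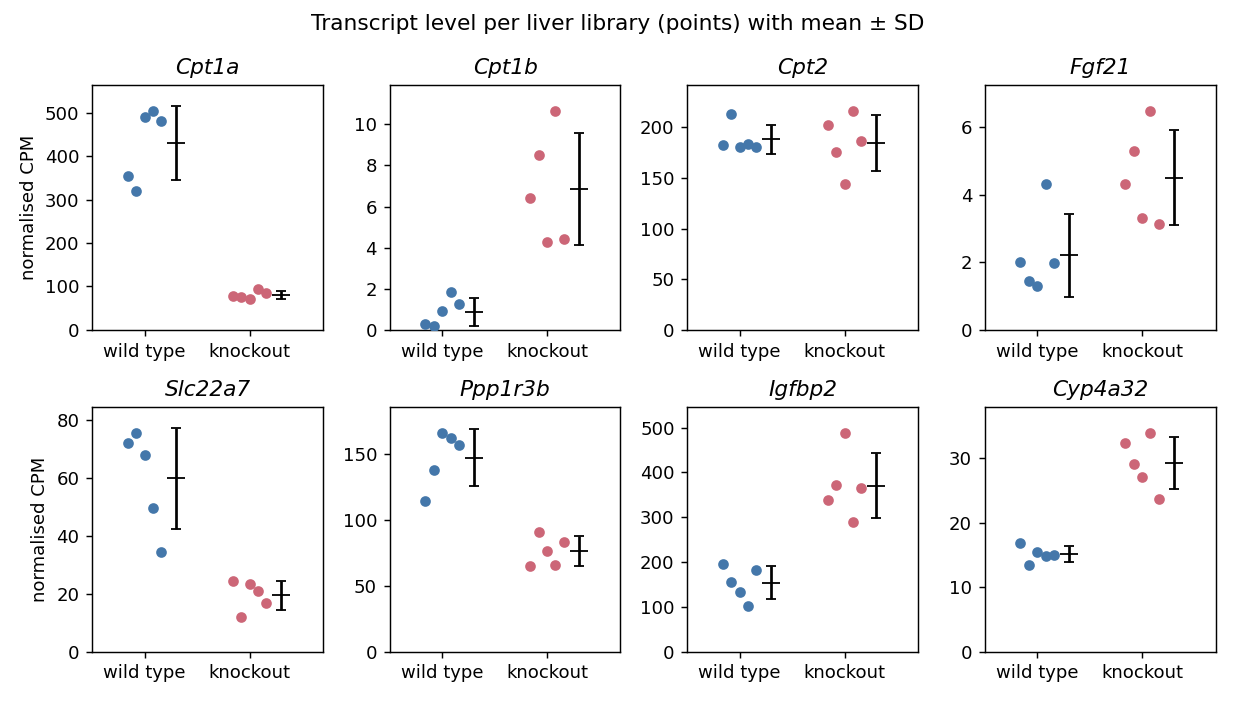
Normalised CPM (linear vertical axes from 0) of 8 genes in each wild type and knockout liver library. Points are libraries and bars are mean ± SD (n = 5 each). The groups do not overlap for Cpt1a, Cpt1b, Slc22a7, Ppp1r3b, Igfbp2 and Cyp4a32, and overlap for Cpt2 and Fgf21.

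Of 13619 genes tested, 18 had a changed level, 11 higher and 7 lower in the knockout, and 14 of them changed at least 2-fold. Among the genes that fell was Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, from 148 ± 21.5 to 76.3 ± 11.3 CPM (log2 fold change -0.95 ± 0.14, adjusted p = 0.018). The organic anion transporter gene Slc22a7 fell from 59.9 ± 17.5 to 19.5 ± 5.11 CPM. Gna14 (log2 fold change -2.08 ± 0.26), Lrtm1 (-1.92 ± 0.27) and the hepcidin gene Hamp2 (-2.19 ± 0.28) fell as well. Hamp2 has a close paralog and overlaps Gm44662 on the opposite strand, so its counts are less certain. Lrtm1 and Ppp1r3b also overlap genes on the opposite strand, Cacna2d3 and Gm45469, which did not pass the filter.

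Igfbp2, a secreted binding protein of insulin-like growth factors, rose from 154 ± 37.2 to 371 ± 73.1 CPM (log2 fold change 1.27 ± 0.19, adjusted p = 0.018). Elovl2, an elongase of polyunsaturated fatty acids, rose from 455 ± 10.6 to 688 ± 50.9 CPM (0.60 ± 0.10, adjusted p = 0.048). The cytochrome P450 gene Cyp4a32 rose 1.93-fold, to 29.3 ± 4.10 CPM (adjusted p = 0.010), although Cyp4a genes are near copies of each other and reads can be split among them. Tmem86a (1.33 ± 0.18), Trpm4 (1.31 ± 0.21), Wdfy4 (1.18 ± 0.17), Serinc2 (1.02 ± 0.16) and Cntnap1 (2.24 ± 0.38) rose as well, given as log2 fold changes with their SE. On the opposite strand Wdfy4 overlaps Lrrc18, and Cntnap1 overlaps Ccr10 and Plekhh3. Trpm4 (mean log2 CPM 1.57) overlaps the more abundant Rpl14-ps1 (4.37) there. The remaining rises were in the transcripts Gm15441 and B930025P03Rik, both chosen after their values were seen. Gm15441 rose from 0.707 ± 0.15 to 8.98 ± 4.93 CPM (adjusted p = 0.0050). It is annotated as antisense to Txnip, on chromosome 3 at 96555765 to 96566801, and the counts cannot assign reads to a strand with certainty, since strand is not stated. Txnip itself was at 120.3 ± 34.4 and 121.4 ± 44.3 CPM.

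For all 18 genes the libraries of the 2 genotypes did not overlap, which held for 143 of the 13619 genes (1.05%) where chance gives 0.79%. Only Cpt1a, Gm15441, Gna14, Cyp4a32 and Hamp2 kept their call in each of the 10 fits that left out 1 library. Tmem86a lost it without wild type replicate 3 (adjusted p = 0.054). Igfbp2 and Ppp1r3b kept it in 5 of 10 fits each, Cpt1b in 1 of 10 (adjusted p up to 0.108) and Elovl2 in 0 of 10 (up to 0.162), with the direction kept in each. The count itself fell to 9 without wild type replicate 2, 6 without wild type replicate 3, 8 without knockout replicate 2, 6 without knockout replicate 3 and 6 without knockout replicate 5, and DESeq2 called 101 genes.

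Fgf21, which encodes a hormone secreted by the liver, was at 2.21 ± 1.22 CPM in wild type and 4.51 ± 1.40 CPM in knockout livers (SD, n = 5 each). Its log2 fold change was 1.01 ± 0.32 (SE, edgeR adjusted p = 0.594). An exact two-sided permutation test of its log2 CPM gave p = 0.032, where edgeR gave an unadjusted p = 0.0085. Knockout libraries lay between 3.14 and 6.48 CPM. Only 2 of 5 exceeded the highest wild type library, replicate 4, at 4.32 CPM, with knockout replicate 1 just below it at 4.31 CPM. The other wild type libraries lay between 1.29 and 2.00 CPM, below every knockout library. Without wild type replicate 4 the log2 fold change was 1.41 (adjusted p = 0.087). The Fgf21 difference thus did not pass the test over all genes, and none of 23 alternatives called it (adjusted p from 0.087 to 0.991).

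Of the 46 gene lists tested, 25 moved with camera's preset correlation, 7 higher and 18 lower. None passed with an estimated correlation (adjusted p from 0.368 to 0.707 among the 25), where 6 lists had an unadjusted p under 0.05. Fry called 0 lists in 1 direction (6 with an unadjusted p under 0.05) and 8 for change in either direction. The exact permutation of list means called 0 (5 with an unadjusted p under 0.05). The group statements that follow rest on the preset correlation. Of the 25 lists, 11 kept their call in each of the 10 fits that left out 1 library, and the libraries without which the others lost it are named with each list. In 0 of the 25 lists did the list means of the wild type and knockout libraries lie fully apart.

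Genes of fatty acid oxidation were higher as groups. Of 31 measured PPARα targets, genes driven by the fatty acid receptor of the liver, 24 had a positive log2 fold change (median 0.15, camera adjusted p = 9.9e-09, adjusted p = 0.405 with an estimated correlation). No member passed over all genes and 3 passed adjusted over the list alone. These were Ehhadh, a bifunctional enzyme of peroxisomal β-oxidation (0.89 ± 0.19), Tmem41a (0.41 ± 0.12) and Retsat (0.61 ± 0.17). The PPARα list mean was 0.25 in wild type replicate 4, above knockout replicates 1, 3 and 5 (0.21, -0.23 and 0.09), and knockout replicate 3 also lay below wild type replicate 5 (-0.04). In the list of peroxisomal and microsomal fatty acid oxidation 22 of 29 members were positive (median 0.12, adjusted p = 5.9e-06, adjusted p = 0.405 with an estimated correlation), with 1 member passing over all genes, Cyp4a32, and 3 adjusted over the list alone. Its list mean was -0.19 in knockout replicate 3 and 0.09 in wild type replicate 4, so the genotypes overlapped there too. Mitochondrial fatty acid oxidation had 17 of 24 members positive (median 0.11, adjusted p = 3.3e-05, adjusted p = 0.368 with an estimated correlation). Its changed member was Cpt1b, and Hadhb (0.41 ± 0.11) passed only adjusted over the list alone, which gave 2. The mean log2 fold change of this list, 0.26, includes Cpt1b at 2.88, and a mean without Cpt1b was not taken. The CPT1 and carnitine list, without Cpt1a, was positive in 7 of 10 members (median 0.06, adjusted p = 0.016, adjusted p = 0.452 with an estimated correlation), and 1 passed over all genes and 2 adjusted over the list alone, Cpt1b and the carnitine transporter gene Slc22a5 (0.48 ± 0.15). Lipid droplet and triglyceride genes were positive in 18 of 28 (adjusted p = 0.013, adjusted p = 0.524 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. The mean log2 fold change of the carnitine list was 0.375 with Cpt1b and 0.097 over its other 9 members, so most of it came from Cpt1b. The carnitine call was lost without wild type replicate 1 or 3 or knockout replicate 1, 2 or 4 (adjusted p from 0.051 to 0.183). The lipid droplet call was lost without wild type replicate 2 or 3 or knockout replicate 4 (adjusted p = 0.061, 0.115 and 0.275). Its list mean differed by 0.20 over all libraries, by 0.33 without wild type replicate 4 and by 0.13 without knockout replicate 4.

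Genes of fatty acid synthesis and glucose use were lower as groups. In the fatty acid synthesis list 20 of 25 members were negative (median -0.28, adjusted p = 3.7e-07, adjusted p = 0.422 with an estimated correlation). None passed over all genes. Adjusted over the list alone, 5 lower and 1 higher member passed. The stearoyl-CoA desaturase gene Scd1 was at 826.7 ± 830.8 and 102.8 ± 57.8 CPM, with a log2 fold change of -3.01 ± 0.60 (adjusted p = 0.106 over all genes). Thrsp was at -1.47 ± 0.27, the pyruvate kinase gene Pklr at -1.14 ± 0.22, and Srebf1, which encodes a transcription factor of lipogenesis, at -0.62 ± 0.14, as was Tkfc (-0.62 ± 0.17). The exception in direction was the desaturase gene Fads2, at 0.84 ± 0.25. The list mean per library was 0.79 in wild type replicate 4 against -0.06 to 0.12 in the other wild type libraries, and -0.74 in knockout replicate 2 against -0.17 to 0.08 in the other knockouts. The difference in list mean was -0.40 over all libraries, -0.25 without wild type replicate 4 and -0.26 without knockout replicate 2, with the call kept in both. Glycolysis and glucose uptake genes were negative in 18 of 25 (adjusted p = 0.0018, adjusted p = 0.422 with an estimated correlation), with 1 member passing over all genes and 3 adjusted over the list alone, among them Pklr and Khk (-0.62 ± 0.18). That call was lost without wild type replicate 4 (adjusted p = 0.051), where the difference in list mean went from -0.15 to -0.09. Gluconeogenesis and glycogen genes were negative in 16 of 23 (adjusted p = 0.032, adjusted p = 0.368 with an estimated correlation). Of these Ppp1r3b passed over all genes, and 2 passed adjusted over the list alone, Ppp1r3b and Pygl (-0.58 ± 0.15). The members went both ways, with the glycogen synthase gene Gys2 at 0.42 ± 0.14 and Pck1 at 0.47 ± 0.20. The call was lost without wild type replicate 1 or 4 or knockout replicate 1, 2 or 3 (adjusted p from 0.053 to 0.115), and the difference in list mean of -0.07 became -0.03 without wild type replicate 4 and -0.04 without knockout replicate 3. Cholesterol synthesis genes were negative in 23 of 25 (adjusted p = 0.0020, adjusted p = 0.635 with an estimated correlation), none passing over all genes or adjusted over the list alone. That call rested on single libraries. It was lost without wild type replicate 4 (adjusted p = 0.239) or knockout replicate 2 (adjusted p = 0.489). Wild type list means ran from -0.49 in replicate 5 to 0.66 in replicate 4, and knockout list means from -0.77 in replicate 2 to 0.42 in replicate 3. The difference in list mean was -0.23 over all libraries, and -0.10, -0.39, -0.07 and -0.37 without wild type replicates 4 and 5 and knockout replicates 2 and 3.

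Genes of protein folding and of proteins secreted by hepatocytes were also lower as groups. Of 25 endoplasmic reticulum chaperones and folding enzymes 23 were negative (median -0.26, adjusted p = 7.7e-11, adjusted p = 0.368 with an estimated correlation). None passed over all genes and 5 passed adjusted over the list alone, Pdia6 (-0.42 ± 0.10) and Pdia3 (-0.42 ± 0.11), which encode disulfide isomerases, Derl3 (-1.49 ± 0.38), the calreticulin gene Calr (-0.45 ± 0.13) and Ero1lb (-0.38 ± 0.11). Acute phase proteins were negative in 29 of 31 (median -0.29, adjusted p = 9.9e-09, adjusted p = 0.368 with an estimated correlation). The list mean was 0.61 and 0.55 in wild type replicates 2 and 3 against 0.03, 0.01 and -0.11 in wild type replicates 1, 4 and 5, which lay below knockout replicate 1 (0.04). The smallest p in that list belonged to the metallothionein gene Mt2 (-1.77 ± 0.50) and to Lcn2 (-1.38 ± 0.41), and 0 members passed over all genes or adjusted over the list alone. Secreted proteins with hormone-like roles were negative in 24 of 32 (adjusted p = 0.032, adjusted p = 0.368 with an estimated correlation), against which Igfbp2 rose, the single member passing over all genes (1) and adjusted over the list alone (1). That call was lost without wild type replicate 1, 4 or 5 or knockout replicate 3 (adjusted p from 0.075 to 0.221), and the difference in list mean of -0.08 became -0.05 without wild type replicate 4 and -0.04 without knockout replicate 3. Lists of amino acid catabolism (34 of 41 negative), pericentral hepatocyte genes (21 of 28), drug-metabolising P450 and conjugation enzymes (23 of 35), hepatocyte identity (18 of 25) and lipoprotein assembly (19 of 26) were lower with camera adjusted p = 0.00037, 0.00074, 0.00095, 0.021 and 0.048. With an estimated correlation their adjusted p = 0.422, 0.452, 0.439, 0.422 and 0.422. In none of these 5 lists did a member pass over all genes or adjusted over the list alone. The P450 list mean was 0.41 and 0.42 in wild type replicates 4 and 5 and -0.51 and -0.32 in knockout replicates 3 and 5. The other wild type libraries (-0.05, -0.06 and -0.01) lay near knockout replicates 1 and 2 (-0.03 and 0.01) and below knockout replicate 4 (0.15). In the pericentral list knockout replicate 4 (0.26) lay above 4 of 5 wild type libraries. Amino acid catabolism lost its call without wild type replicate 1 (adjusted p = 0.058). Hepatocyte identity kept it in 5 of 10 fits, losing it without wild type replicate 1 or 3 or knockout replicate 2, 3 or 4 (adjusted p up to 0.132). Lipoprotein assembly kept it in 4 of 10, losing it without wild type replicate 1, 2, 4 or 5 or knockout replicate 2 or 3 (up to 0.267), and its difference in list mean went from -0.10 to -0.07 without knockout replicate 3.

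Extracellular matrix and fibrosis genes were negative in 31 of 34 (median -0.38, adjusted p = 9.0e-09, adjusted p = 0.422 with an estimated correlation). The smallest p belonged to Lum (-0.71 ± 0.22) and Sparc (-0.44 ± 0.14), and 0 members passed over all genes or adjusted over the list alone. The libraries of the genotypes overlapped. The list mean was 0.50 in knockout replicate 4, above 4 of 5 wild type libraries, and -0.05 and -0.31 in wild type replicates 1 and 2, against 0.22 to 0.59 in wild type replicates 3, 4 and 5 and -0.58 to -0.17 in the other knockouts. These high means fall in libraries that lie on 1 side of the first principal component described further on. Markers of other liver cell types were lower beside them, namely stellate cells and fibroblasts (20 of 21 negative, median -0.26, adjusted p = 5.6e-05), cholangiocytes (12 of 14, median -0.40, adjusted p = 0.0020), Kupffer cells and macrophages (25 of 31, median -0.11, adjusted p = 0.036) and endothelial cells (21 of 23, median -0.13, adjusted p = 0.040). With an estimated correlation these had adjusted p = 0.368, 0.452, 0.504 and 0.707. The stellate list mean was -0.09 and -0.11 in wild type replicates 1 and 2, against 0.27 to 0.38 in wild type replicates 3, 4 and 5. It was 0.19 in knockout replicate 4, against -0.33 to -0.16 in the other knockouts. The cholangiocyte call was lost without wild type replicate 4 (adjusted p = 0.189), whose list mean was 0.85 against -0.31 to 0.16 in the other wild type libraries, and the difference in list mean then went from -0.28 to -0.10. The Kupffer cell call was kept in 4 of 10 fits and lost without wild type replicate 1, 4 or 5 or knockout replicate 2, 3 or 5 (adjusted p up to 0.382). Its difference in list mean of -0.16 became -0.09 without wild type replicate 5 and -0.26 without knockout replicate 4. The endothelial call was kept in 5 of 10 and lost without wild type replicate 1, 4 or 5 or knockout replicate 2 or 3 (up to 0.612). Its difference of -0.12 lay between -0.23 without wild type replicate 2 and -0.04 without knockout replicate 2, and was -0.07, -0.06, -0.06 and -0.19 without wild type replicates 4 and 5 and knockout replicates 3 and 4. Inflammatory cytokines and chemokines were negative in 20 of 24 (adjusted p = 0.011, adjusted p = 0.500 with an estimated correlation). The cytokine call was lost without wild type replicate 4 (adjusted p = 0.253) or knockout replicate 2 (adjusted p = 0.068). Wild type replicate 4 had a list mean of 0.64, while wild type replicates 2 and 3 (-0.16 and -0.22) lay below knockout replicates 1, 4 and 5 (0.04, 0.10 and 0.01), and the difference in list mean of -0.22 became -0.08 without wild type replicate 4. In these cell type and cytokine lists 0 members passed over all genes or adjusted over the list alone. Interferon response genes went the other way, with 27 of 34 positive (median 0.20, adjusted p = 1.1e-07, adjusted p = 0.368 with an estimated correlation). None passed over all genes and 3 passed adjusted over the list alone, Oas1g (1.63 ± 0.33), Oas1a (1.16 ± 0.29) and Ifi44 (0.95 ± 0.25), of which the Oas1 genes are close paralogs. The interferon list mean was 0.42 and 0.26 in knockout replicates 3 and 5, against 0.06, -0.04 and 0.01 in replicates 1, 2 and 4. Wild type libraries ran from -0.29 to -0.04. The difference in list mean of 0.29 became 0.22 without knockout replicate 3, with the call kept. The list of RNA quality and handling stress was also higher (13 of 18 positive, median 0.20, adjusted p = 0.013, adjusted p = 0.504 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. That call was lost without wild type replicate 1, 2 or 3 or knockout replicate 5 (adjusted p from 0.055 to 0.207). Its difference in list mean of 0.20 became 0.10, 0.09, 0.32 and 0.32 without wild type replicates 2, 3, 4 and 5, and 0.31 and 0.10 without knockout replicates 2 and 5.

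**Figure D2:**
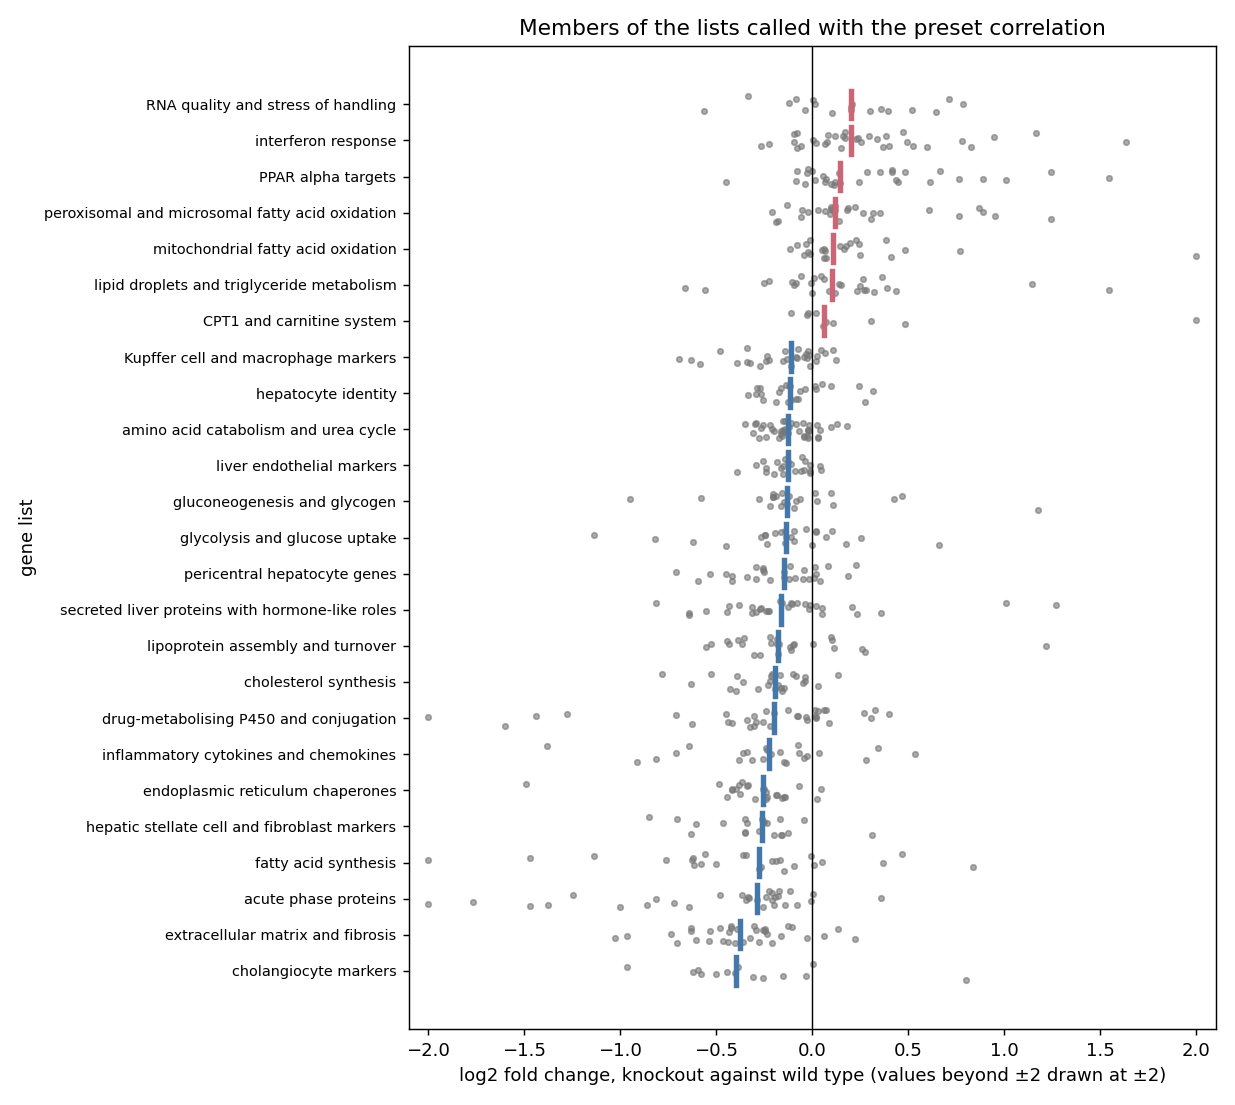
Log2 fold change (knockout against wild type, horizontal axis) of each measured member (grey points) of the 25 lists that moved with the preset correlation, with the list median as a coloured bar. 5 points beyond the axis are drawn at its ends. Medians run from -0.40 for cholangiocyte markers to 0.20 for the RNA quality and interferon lists.

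The other 21 lists did not pass (camera adjusted p from 0.141 to 0.940). They included ketogenesis (7 of 10 positive, median 0.04), nuclear-encoded oxidative phosphorylation (33 of 47 negative, median -0.05), the circadian clock (12 of 19 positive, median 0.05) and the integrated stress response (20 of 29 negative, median -0.12). Median, mean and test differed in sign for adipocyte markers, the citric acid cycle and NRF2 genes.

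The libraries did not separate by genotype along their first principal component, which held 34.2% of the variance. Wild type replicates 1 and 2 lay at -38.4 and -41.8, and the other 3 wild type libraries between 25.1 and 31.0. Knockout replicates 2, 3 and 5 lay at -22.4, -7.65 and -15.4, and replicates 1 and 4 at 18.4 and 23.1. Without wild type replicates 1 and 2, a choice made after seeing the data, 10 genes were called, 7 of them among the 18 (Gm15441 and Hamp2 were not, each at adjusted p = 0.067), and 14 of the 25 lists kept their call. The wild type libraries left in that fit all lay on the same side of the component, so genotype and component are partly confounded in it.

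**Figure D3:**
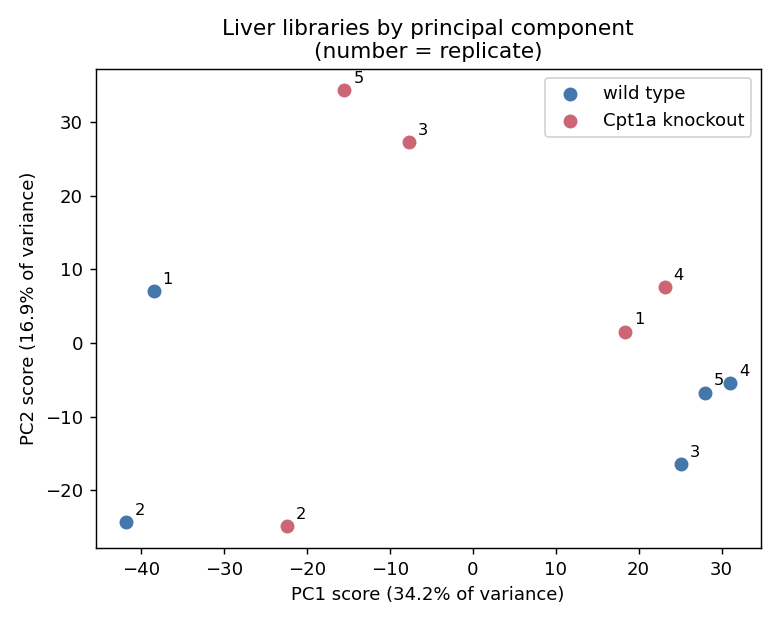
Scores of the 10 liver libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, 34.2% and 16.9% of variance. Colours give the genotype and numbers the replicate. Both genotypes occur on each side of the first component.

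The authors' deposited table gave p under 0.05 for 806 genes, 430 higher and 376 lower in the knockout. All 18 genes called here had such a p and the same sign there. The deposited p of Cpt2 (0.842) and Txnip (0.956) lay near their unadjusted edgeR p here (0.839 and 0.961), so the deposited p is likely unadjusted. The like count here, at an unadjusted edgeR p under 0.05, was 656 genes, 349 higher and 307 lower. Adjusted here over the 24413 genes with a count, the deposited p-values called 82 genes, including all 18. In the authors' deposited table the log2 fold change of Cpt1a was -1.99 and that of Fgf21 0.51 (p = 0.0024 as deposited).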

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

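The tests of GC content and length, of cell types and of Txnip were chosen after the result or closely related values were seen, and the counts over other splits of the libraries were set before.

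In 98 groups of 5 values that the text rests on, 6 had a library far from the others, where chance gives about 1 in 20. Among wild type libraries, replicate 4 had 4.32 CPM of Fgf21 against 1.29 to 2.00 in the others (gap over range 0.766). The same library was highest for the mean of the fatty acid synthesis list (0.794) and of the lipid droplet list (0.765). Wild type replicate 2 had 212.7 CPM of Cpt2 against 180.2 to 182.9 (0.916). Wild type replicate 3 had 18.1% of its counts in the 10 genes most abundant over all libraries, against 19.3% to 19.8% (0.721). Knockout replicate 4 had 25200273 counts against 23990970 to 24315598 in the others (0.727).

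The real split of the libraries called 18 genes. Of 100 splits of the 10 libraries into 5 and 5, out of 126 possible, 2 gave at least as many, the real one included. This share is under 0.05 over the splits that were run. Since not every possible split was run, the share does not firmly exclude chance for this count. The highest other split gave 3124 genes and set wild type replicates 3, 4 and 5 and knockout replicates 1 and 4 against the rest. A count that many times the real one points to a structure of the samples that crosses genotype, and it is the division along the first principal component.

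For that division, GC content and transcript length explained 23.5% of the variance of the gene loadings, which is consistent with a part played by such bias. Removing each library's trend left 58.6% of the variance of the scores, which argues against this bias as the whole of it. Wild type replicates 1 and 2 then still lay at -26.4 and -33.2, opposite replicates 3 to 5 at 16.7 to 24.9. Since the labels give no group for the division, no biological explanation was tested, and what produces the rest stays open.

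The number of lists that moved was 25 in the real split. Of the 100 splits, 4 gave at least as many, the real one included, and the highest other gave 28. That share is under 0.05 by a small margin. Since not every possible split was run, it does not firmly exclude chance. The other splits called a median of 13 lists, so many single list calls with the preset correlation could arise with no effect of genotype. A list called with the preset correlation is therefore weak evidence on its own, and 0 lists passed with an estimated correlation.

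Matrix and stellate lists were lower in the knockout together with markers of cholangiocytes, endothelial cells and macrophages. Lists of other immune cells were not called, namely neutrophils (median -0.35, camera adjusted p = 0.171), B and plasma cells (-0.22, 0.309), T and NK cells (-0.09, 0.328) and MHC class II genes (0.01, 0.784). A lower share of all such cells would lower them alike, but the stellate list mean minus that of the endothelial and macrophage lists differed by -0.157 between genotypes (exact two-sided permutation p = 0.111), and the MHC class II list mean by 0.031 with a library SD of 0.30 in wild type. Neither value is beyond its spread, so a lower share and a lower level in stellate cells cannot be told apart here. An effect of genotype on the matrix genes stays among the open explanations.

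The rise of Gm15441 could come from reads of Txnip, which it overlaps on the opposite strand. The Txnip log2 fold change had an upper 95% bound of 0.498, below the rise of at least 1 set for a Gm15441 level that follows Txnip. The bound argues against that form only. In the knockout Gm15441 was at 8.98 ± 4.93 CPM beside 121.4 ± 44.3 CPM of Txnip. A small part of the Txnip reads counted as Gm15441 would hardly move Txnip, so the bound cannot decide on that. A small part of constant size would give Gm15441 the log2 fold change of Txnip, 0.01, but Gm15441 was at 3.65 ± 0.40 (SE). Knockout replicates 2 and 3 had 84.2 and 83.8 CPM of Txnip beside 15.7 and 5.23 CPM of Gm15441. Wild type replicates 4 and 5 had 158.0 and 153.4 CPM of Txnip beside 0.96 and 0.64 CPM of Gm15441. These values argue against a part of constant size. Gm15441 was between 3.21 and 15.7 CPM in the knockout libraries and below 0.97 CPM in wild type. A part that varies between libraries was not tested, so a rise of Gm15441 itself tied to the genotype remains a hypothesis.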

How the results depend on the processing

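The surrogate variables, the GC content and length offset, the removal of wild type replicates 1 and 2, and the exact permutation of list means were chosen after seeing the data, and the other alternatives before. The 18 called genes kept their direction in all 23 alternatives, and Cpt1a was called in each (log2 fold change from -2.61 to -2.35). Fgf21 was called in none (0.83 to 1.41). DESeq2 called 101 genes, 56 higher and 45 lower, among them all 18. With 1 surrogate variable 43 genes were called (24 higher, 19 lower, 17 shared) and with 2 there were 58 (32 higher, 26 lower, 15 shared). The GC content and length offset gave 11 lower genes (22 in all, 17 shared). Without wild type replicates 1 and 2 there were 10 genes, 4 of them higher. The cause of these moves was not tested. The last fit has fewer libraries, yet 1954 genes had an unadjusted edgeR p under 0.05, against 656 with all libraries. Its wild type libraries all lie on the same side of the first principal component, while the knockouts lie on both. Genotype and that component are thus partly confounded there. Leaving out 1 library gave 6 to 21 genes, and the count was 12 without wild type replicate 1. The range was 2 to 14 for higher genes and 3 to 10 for lower ones, and 16 to 26 for lists, with the lowest without wild type replicate 1. Cpt2, never called and between -0.0906 and 0.0512 with 1 library left out, had opposite signs with total-count scaling (0.0696), without wild type replicate 2 (0.02), without knockout replicate 3 (0.0512) and without wild type replicates 1 and 2 (0.0309). Total-count scaling shifted the median of all genes by 0.09.

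The replicate number as a block gave 26 genes, 13 lower and 13 of them shared. Same-numbered libraries correlated between -0.41 and 0.43, over 0.1 for 2 of 5 numbers, and 4 of 10 libraries correlated best with their own number. These values give no clear sign that the number pairs the samples, but they cannot exclude it. Camera with an estimated correlation and the exact permutation of list means each called 0 of the 46 lists, with 6 and 5 at an unadjusted p under 0.05. No called list changed direction. Of the 25, 11 kept their call in each of the 10 fits without 1 library. In the simulations of this comparison, run at its depth and replicate number, 17.6% of genes changed 1.5-fold were recovered, and what limited recovery was not separated.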

Other observations

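The tests of KEGG maps and of the extracellular class were chosen after related results were seen. The sex-biased lists and the edgeR test were set before, but what is shown from them was picked after values were seen. Of 325 KEGG pathway maps annotated in the deposited table, 14 moved with camera's preset correlation, 13 lower and 1 higher, and 0 with an estimated one (smallest adjusted p = 0.997). Genes of complement and coagulation were negative in 74 of 86 (median log2 fold change -0.16, camera adjusted p = 0.00034), and those of protein processing in the endoplasmic reticulum in 118 of 158 (median -0.08, adjusted p = 0.0067). Linoleic acid metabolism, whose 5 members with the smallest p are Cyp2c genes that are close copies of each other, was negative in 22 of 27 (median -0.19, adjusted p = 0.00034). The higher map was fatty acid degradation (26 of 45 positive, median 0.06, adjusted p = 0.036). Some maps close to lists that moved did not pass, namely PPAR signalling (adjusted p = 0.107), peroxisome (0.699), glycolysis and gluconeogenesis (0.070) and steroid biosynthesis (0.083). ECM-receptor interaction, close to the matrix list, did pass (40 of 53 negative, camera adjusted p = 0.013). Unlike the PPARα list, the PPAR signalling map holds Cpt1a itself (-2.43) and Scd1 (-3.01). The fatty acid degradation map also holds Cpt1a.

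Because several of these groups encode secreted proteins, a candidate explanation is that transcripts of secreted proteins may be lower as a class. The 614 genes annotated to the extracellular region or space were lower in the knockout by -0.082 on the log2 scale relative to expression-matched genes (exact two-sided permutation p = 0.0317, n = 5 each, unadjusted). This class includes members of lists already seen to be lower. With all listed genes left out, the difference was -0.064 over 510 genes (exact permutation p = 0.0635), which does not pass, so the class effect outside those lists remains undecided.

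Among lists that camera did not call, that of female-biased liver genes had members in both directions. Fry called it for change in either direction (fry adjusted p = 0.012). Adjusted over the list alone, 2 were higher and 4 lower and none passed over all genes, with Cyp17a1 at -1.26 ± 0.32, Cyp2b13 at -2.95 ± 0.84 and Gpc1 at 1.13 ± 0.22 (log2 fold change ± SE). The list mean split within wild type, with 1.07 and 0.85 in replicates 4 and 5 against -0.18, -0.57 and -0.34 in replicates 1 to 3, and was 0.67 in knockout replicate 4. The male-biased list ran the other way in wild type (-0.89 and -0.71 in replicates 4 and 5, 0.57, 0.64 and 0.49 in replicates 1 to 3) and was -0.53 in knockout replicate 4. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y, looked up after values were seen, were present in every library. They were at 9.68 to 15.1, 3.51 to 11.5, 9.52 to 35.0 and 7.66 to 35.2 CPM. The X-linked Xist had 24 counts over the wild type and 13 over the knockout libraries. These values argue against a mix of sexes among the libraries. Cyp2b13 was at 4.38 ± 5.42 CPM in wild type, with 13.5 CPM in replicate 5, 5.32 in replicate 4 and 0.62 to 1.69 in the others, so its fold change rests on libraries that stand apart. Cebpb, a transcription factor gene in the integrated stress response list, was at 1.49 ± 0.27 (edgeR adjusted p = 0.067 over all genes). Knockout replicate 2 had 9.33% of its counts in mitochondrially encoded genes, against 5.30% to 6.58% in the other knockout libraries.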
